A study of Homo sapiens with 6 samples.

How the data were processed

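RNA of human monocyte-derived immature dendritic cells was measured on Affymetrix HG-U133 Plus 2 arrays, in 2 arrays for each of 3 groups. Per the labels' protocols, CD14-positive cells were cultured for 5 days with IL-4 at 50 ng/ml and GM-CSF at 1000 IU/ml. Stimulation began on day 7 and lasted 48 hours, and total RNA was amplified with a two-cycle cDNA kit before labelling. The deposited values are log2 probe set summaries, made by the authors with Affymetrix Expression Console and RMA per the submitters' processing notes, with versions not given in the sources used here. RMA subtracts background, makes the arrays' distributions alike and sums the probes of a probe set, so it removes overall shifts between arrays and compresses differences of dim genes. The array medians were 5.462 to 5.479, and the sorted values of any pair of arrays lay within 0.135 of each other. Arrays give no read depth. The number of arrays limits the precision.

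The table has 54675 rows, of which 62 are control rows. The platform annotation gave 1 gene symbol for 41097 probe sets, several for 1801 and none for 11777, and no gene was named from a probe set with several. Of those with 1 symbol, 41043 matched the gene table by Entrez identifier, and 0 symbols changed.

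In 1118 rows the names appeared out of step with the values. They are the rows whose place differs between sort orders that put the separator before the suffix in different places. In 437 of these probe sets, the mean level had a correlation of 0.0386 with the other probe sets of the named gene in place, and of 0.3328 for the value 1 row further on. The other displaced rows could not be checked this way. In 28983 other probe sets it was 0.46 in place, and in 1 of 179 blocks of 300 rows a neighbouring row matched better. These rows were left out, a choice made after the data were examined, and both the deposited and a realigned naming were run as alternatives. Control rows were left out too. One of the rows concerned carries the name of CXCL8.

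Each gene was represented by its probe set with the highest mean over the 6 arrays. Of 19642 genes, the 11785 at or above the 40th percentile of that mean, a level of 5.689, were kept. Genes of the Y chromosome and of X inactivation were left out of every step. Values were tested with limma 3.58.1 in R 4.3.3, with 3 group means over all 6 arrays, moderated variances without a trend and Benjamini-Hochberg adjustment per comparison. A gene was called at an adjusted p under 0.05, two-sided. An exact permutation of 2 arrays against 2 cannot go below a two-sided p of 0.333, so all tests rest on limma's model of the spread. The labels do not say that replicates came from separate donors or cultures, so p-values measure only the spread between these samples, which may be technical.

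The labels number the replicates 1 and 2 in each group and do not say what the number marks. Arrays of the same number deviated together, with correlations across genes of 0.431 between control and IL-8, 0.502 between control and AsnRS and 0.521 between IL-8 and AsnRS. The first principal component, with 43.2% of the variance, separated the numbers, the next, with 22.7%, separated IL-8 from the rest, and 281 genes differed between the numbers. The fit without a block stays as the one chosen before the data were examined, and the fit with the number as a block is printed beside it where it changes a call.

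For gene lists, 34 were fixed before the data were examined, covering dendritic cell state, signalling, metabolism, stress, cell cycle and markers of other blood cells. The 33 with at least 5 kept genes were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. With an estimated correlation no list passed in any comparison. The list of IL-8 receptors and ligands had too few kept genes. Named genes follow a rule fixed before the data were examined. Per comparison and direction they are the 12 largest differences among called genes, or, where fewer than 6 pass, the largest differences up to 6 among genes whose groups do not overlap, given as values. With 2 arrays against 2, 33.3% of genes do so by chance. The observed share was 28.6% for AsnRS against control, 33.2% for IL-8 against control and 36.6% for AsnRS against IL-8. Groups that do not overlap are thus no evidence of a change. CXCR1, CXCR2, CXCL8 and NARS1 are always named, as are up to 4 members of a described list. Genes whose level follows the donor's genotype, and uncharacterised loci, are never named.

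The fits were tested on simulated data with the real means, spreads and replicate number effects, over 11785 genes, of which 67 were changed by 0.5, 67 by 1 and 66 by 2 on the log2 scale. For AsnRS against control, the fit without a block called 53.7% of genes changed by 0.5 on the log2 scale and 97% of those changed by 1, with 0 unchanged genes called. With the block it called 98.5% and 100%, with 16 unchanged genes called. For IL-8 against control the fit without a block called 46.3% and 98.5%, with 0 unchanged genes, and with the block 100% and 100%, with 17. For AsnRS against IL-8 it called 59.7% and 98.5%, with 1 unchanged gene, and with the block 98.5% and 100%, with 19. With so many changed genes the adjustment is less strict than where few genes change. These shares therefore do not carry over to the data, and an absence of calls there does not exclude changes of 1. CLEC5A, at 1.07 for IL-8 against control, was not called by limma without a block (adjusted p = 0.0666). The check of row names was tested on simulated displaced rows. Correlations of effects were set against 100 simulations of unchanged groups with shared controls, with the spread within replicate numbers or between all arrays, and overlaps against 100 with the spread between all arrays and 100 with the block. Alternatives were the filter, the probe set rule, further normalization, an intensity trend, the samples in the fit, the replicate block, array weights and leaving out each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.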

Results

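Gene expression was measured in human immature dendritic cells, antigen-presenting cells grown from the CD14-positive cells of peripheral blood with IL-4 and GM-CSF. The cells were left unstimulated, were stimulated with IL-8, or were stimulated with recombinant asparaginyl-tRNA synthetase (AsnRS) of the filarial nematode Brugia malayi, an enzyme that charges tRNA with asparagine. IL-8 was given at 1 mg/l, and the cells were harvested after 48 hours. The labels give no dose for AsnRS, so differences between the stimuli cannot be told apart from a difference in dose. Each of the 3 groups had 2 arrays, 6 in all, and the number of arrays limits the precision of every value below. The arrays were much alike. Pearson's r across genes was 0.9943 to 0.9959 between the replicates of a group and 0.9962 to 0.9977 between arrays of different groups with the same replicate number. Differences are log2 values, with the standard error (SE) of the limma fit and n = 2 arrays per group.

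The direct comparison of AsnRS with IL-8 asked whether the nematode enzyme, which acts on IL-8 receptors, gave the expression pattern of IL-8 itself. CXCL8, the gene of IL-8, was the 1 gene called without a replicate block, and 6 genes were called with one. Its level was 6.43 ± 0.10 (SD, n = 2) with AsnRS, 5.12 ± 0.12 with IL-8 and 5.52 ± 0.06 in the controls. The log2 difference between AsnRS and IL-8 was 1.31 ± 0.09 (SE), with an adjusted p of 0.0185. That call was lost without any 1 of the 6 arrays, with no filter on low genes (adjusted p = 0.0583) and with displaced row names realigned (0.0951), and with the names as deposited the difference was -0.03 (0.976). By camera the interferon-stimulated list lay higher with AsnRS, and the cell cycle and cholesterol synthesis lists lay higher with IL-8. With an estimated correlation each of these 3 calls was lost (adjusted p = 0.637), and by fry's directional test the adjusted p was 0.447, 0.447 and 0.459.

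Of the 39 interferon-stimulated genes kept, which serve in antiviral defence, 36 lay higher with AsnRS than with IL-8, with a mean log2 difference of 0.186 and an adjusted p of 9.29e-10 (adjusted p = 0.637 with an estimated correlation). The differences were 0.59 ± 0.11 for IFIT2, 0.53 ± 0.11 for IFIT1, 0.47 ± 0.08 for IFI27 and 0.42 ± 0.12 for IFIT3, and no single member passed the threshold over all genes. Adjusted over the list alone, 10 of the 39 members passed. The T and NK cell list moved the same way, with a mean of 0.107 over 20 genes and an adjusted p of 0.0276 (adjusted p = 0.975 with an estimated correlation). Of its members 13 lay above 0 and 7 below. GZMA, a granzyme of cytotoxic lymphocytes, differed by 0.58 ± 0.11, CD2 by 0.40 ± 0.08 and NKG7 by 0.30 ± 0.07. The T cell genes CD3D, LCK and CD3E differed by 0.19 ± 0.07, -0.08 ± 0.07 and -0.07 ± 0.08. With the replicate number as a block the T and NK cell list was no longer called, at an adjusted p of 0.0851, nor was it without either IL-8 array or without AsnRS replicate 1 (adjusted p = 0.0536, 0.124 and 0.249). Its mean was 0.071 without IL-8 replicate 2.

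Of the 21 cell cycle genes kept, 17 lay lower with AsnRS than with IL-8, with a mean log2 difference of -0.210 and an adjusted p of 2.78e-09 (adjusted p = 0.637 with an estimated correlation). The differences were -0.75 ± 0.12 for TYMS, which makes thymidylate for DNA synthesis, -0.75 ± 0.11 for CDK1, the kinase that drives mitosis, and -0.59 ± 0.12 for RRM2, a subunit of ribonucleotide reductase. PCLAF, a partner of the replication clamp PCNA that is not on the list, differed by -0.75 ± 0.08 with an adjusted p of 0.128. KIF23, a kinesin of cell division, differed the other way, by 0.59 ± 0.10. Adjusted over the list alone, 4 of the 21 cell cycle genes passed, and 7 with the replicate number as a block. With dim genes removed up to the 60th percentile the list mean was -0.042 and the list was not called (adjusted p = 0.242). The probe sets of TYMS differed by -0.75, -0.67 and -0.03 and those of CDK1 by -0.75, -0.73, -0.51 and 0.33, the last of each being the dimmest. Those of PCLAF differed by -0.75 and, in the dimmer one, -0.14, and those of RRM2 by -0.59 and -0.98.

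The cholesterol synthesis and uptake list was lower with AsnRS than with IL-8 in 15 of its 16 genes, with a mean of -0.172 and an adjusted p of 1.3e-08 (adjusted p = 0.637 with an estimated correlation). INSIG1, a sterol-regulated brake on the pathway, differed by -0.42 ± 0.10, DHCR7 by -0.36 ± 0.10, MSMO1 by -0.29 ± 0.08 and HMGCS1 by -0.26 ± 0.10. The integrated stress response list had a mean of -0.073 over 20 genes and an adjusted p of 0.00247 (adjusted p = 0.637 with an estimated correlation). Its members SLC7A1 and SLC7A11, both amino acid transporters, differed by -0.37 ± 0.08 and -0.33 ± 0.07. The list of LXR and lipid handling genes had a mean of -0.078 over 19 genes and an adjusted p of 0.00292 (adjusted p = 0.866 with an estimated correlation). Within it, lipoprotein lipase (LPL) differed by -0.30 ± 0.07 and its inhibitor ANGPTL4 by 0.37 ± 0.08. In all, 6 of 33 lists passed. With no filter on low genes the stress response and lipid lists were not called (adjusted p = 0.11 and 0.0888), and the lipid list was not called without IL-8 replicate 1 or AsnRS replicate 2 (0.0704 and 0.109), where its mean was -0.039 and -0.041. Without IL-8 replicate 1 the mean of the cholesterol list was -0.102.

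**Figure D1:**
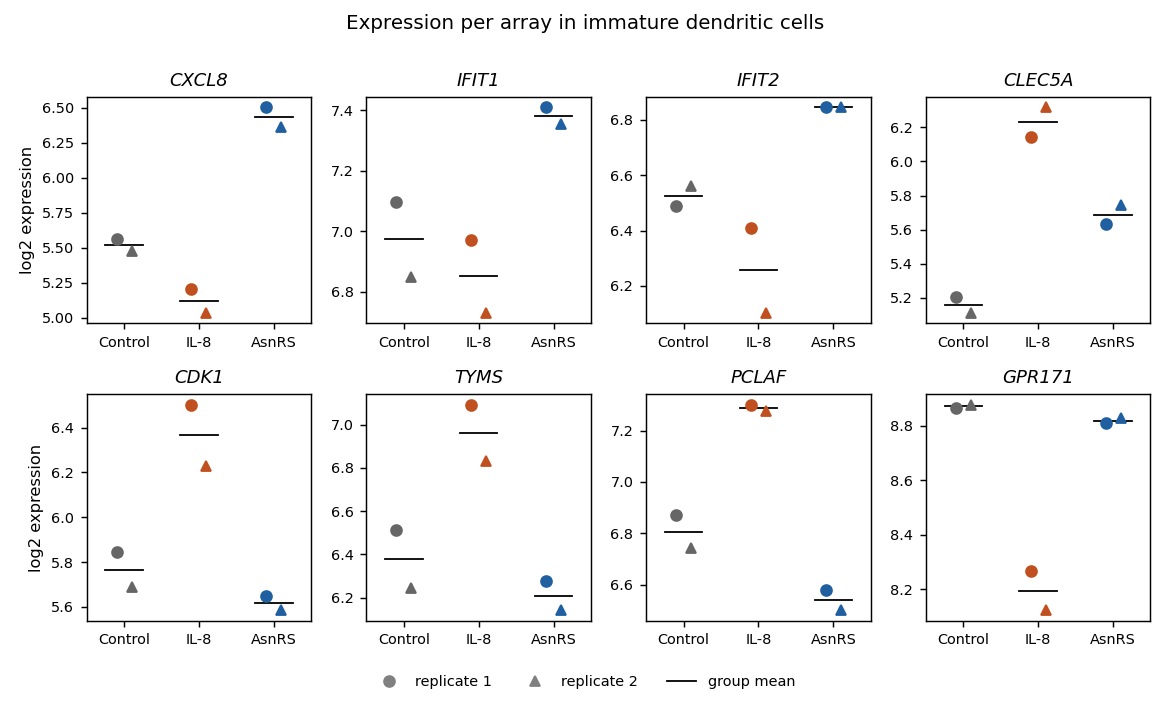
Log2 expression (vertical axes, each panel on its own scale) of 8 genes on each array, by group (horizontal axes). Circles are replicate 1, triangles are replicate 2, and lines are the means of 2 arrays. CXCL8 lies at 6.43 on average with AsnRS and 5.12 with IL-8, and TYMS at 6.21 and 6.96.

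Across 11785 genes, 1 gene passed between AsnRS and IL-8, CXCL8. An unadjusted p under 0.05 was seen for 906 genes, and for 1494 with the replicate number as a block, where evenly spread p-values would give 589. Besides those named above, the largest differences among genes whose groups did not overlap were 0.62 ± 0.07 for GPR171, 0.57 ± 0.10 for NAPEPLD, -0.58 ± 0.13 for CHML and -0.54 ± 0.09 for CLEC5A. With the replicate number as a block 6 genes passed. CXCL8, GPR171 and KIF23 were higher with AsnRS, and CDK1, PCLAF and TYMS were lower. In that fit the adjusted p was 0.000558 for CXCL8, 0.0182 for TYMS and PCLAF, 0.0241 for CDK1 and 0.048 for GPR171 and KIF23. The mean level of CXCL8, 5.689, lies at the limit of the filter, and its level with IL-8 lies below the array medians of 5.462 to 5.479. Whether it lay above background there was not tested, so no fold is given. A second row that may belong to CXCL8 is among the rows left out because names and values appeared out of step, and with those rows realigned the difference was 1.43. Over 23 alternatives its adjusted p ran from 1.1e-06 to 0.976, with 11 past the threshold.

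IL-8 was compared with no stimulation to show what the chemokine alone did to the cells. CLEC5A, a myeloid receptor that signals through DAP12, showed the largest difference, 6.23 ± 0.13 (SD, n = 2) against 5.16 ± 0.07 in the controls. That is a log2 difference of 1.07 ± 0.09 (SE), with an adjusted p of 0.0666, and of 0.0141 with the replicate number as a block. Its control level lies below the array medians of 5.462 to 5.479, and whether it lay above background there was not tested. By camera the cell cycle, stress response, cholesterol, lipid handling, matrix and monocyte lists lay higher with IL-8, and the interferon-stimulated list lay lower. Each of these calls was lost with an estimated correlation (adjusted p = 0.815 to 0.960) and by fry's directional test without the block (0.398 to 0.738), while fry with the block called lipid handling, cell cycle and monocyte (0.0422, 0.0227 and 0.0227).

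Among the 21 cell cycle genes, 17 lay above the controls, with a mean of 0.137 and an adjusted p of 4e-04 (adjusted p = 0.815 with an estimated correlation). CDK1 differed by 0.60 ± 0.11, TYMS by 0.58 ± 0.12, RRM2 by 0.48 ± 0.12 and BUB1B by 0.27 ± 0.14. Adjusted over the list alone, 4 members passed, CDK1, TYMS, RRM2 and MELK, and BUB1B did not. With the 60th percentile filter the list mean was 0.006 and the list was not called (adjusted p = 0.844). The integrated stress response, cholesterol synthesis, LXR and lipid handling and matrix lists each had an adjusted p of 0.00197, with means of 0.099, 0.098, 0.090 and 0.092. With an estimated correlation the adjusted p = 0.815 for stress response and matrix, 0.855 for cholesterol and 0.820 for lipid handling. SLC7A1 differed by 0.51 ± 0.08 and SLC7A11 by 0.34 ± 0.07, INSIG1 by 0.36 ± 0.10, LPL by 0.40 ± 0.07 and ANGPTL4 by -0.46 ± 0.08. TIMP3, an inhibitor of matrix metalloproteinases, differed by 0.53 ± 0.10. The monocyte list, which holds markers of the precursor cells, had a mean of 0.097 over 13 genes and an adjusted p of 0.00953 (adjusted p = 0.815 with an estimated correlation). The NF-kB and inflammatory list had an adjusted p of 0.0377, with a mean of 0.068 and a median of -0.002, and 13 members lay above 0 and 14 below (adjusted p = 0.815 with an estimated correlation). PTX3 differed by 0.69 ± 0.13, G0S2 by 0.49 ± 0.08 and CCL4 by 0.46 ± 0.10, and CXCL8 by -0.40 ± 0.09. With the replicate number as a block this list had an adjusted p of 0.0535, and it was not called without control replicate 1, either IL-8 array or either AsnRS array (adjusted p from 0.0536 to 0.228). The cholesterol mean was 0.027 without IL-8 replicate 1 and 0.168 without IL-8 replicate 2, the lipid handling mean was 0.051 without IL-8 replicate 1, and the stress response mean was 0.061 without control replicate 2.

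Interferon-stimulated genes were lower with IL-8 than in the controls in 27 of 39 cases, with a mean of -0.072 and an adjusted p of 0.0245 (adjusted p = 0.960 with an estimated correlation). PARP14 differed by -0.38 ± 0.07, SAMD9L by -0.33 ± 0.07 and SAMD9 by -0.32 ± 0.07, and IFI6 by 0.36 ± 0.14. The T and NK cell list had a mean of -0.056 and an adjusted p of 0.316. In all, 8 of 33 lists passed between IL-8 and control. Without IL-8 replicate 1, 3 passed, stress response, cell cycle and matrix, and the interferon-stimulated list was also lost without control replicate 1 or IL-8 replicate 2 (adjusted p = 0.337 and 0.0825), where its mean was -0.024 and -0.046. Without control replicate 2 that mean was -0.120. With no filter on low genes 4 passed, interferon-stimulated, cholesterol, lipid handling and cell cycle.

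No gene passed over all genes by limma between IL-8 and control. An unadjusted p under 0.05 was seen for 852 genes, and for 1487 with the replicate number as a block, where evenly spread p-values would give 589. The largest differences among genes whose groups did not overlap were, besides CLEC5A, 0.97 ± 0.13 for CHML, 0.69 ± 0.13 for PTX3, 0.62 ± 0.30 for RBM48 and 0.61 ± 0.07 for the transcription factor ETV5. On the lower side they were -0.82 ± 0.33 for APP, -0.78 ± 0.24 for PPP3R1, -0.76 ± 0.31 for the lysosomal protease CTSZ, -0.76 ± 0.23 for ATG16L2, -0.68 ± 0.07 for GPR171, a G protein-coupled receptor, and -0.66 ± 0.18 for TNKS2. With the replicate number as a block 6 genes passed. CLEC5A, ETV5 and TCF7L2 were higher with IL-8, and GPR171, complement C5 and MOCOS were lower. C5, TCF7L2 and MOCOS are named here after their values were seen.

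AsnRS was compared with no stimulation to show what the parasite enzyme did to the cells. Among genes whose groups did not overlap CXCL8 differed most, with a log2 difference of 0.91 ± 0.09 (SE, n = 2 per group). Its adjusted p was 0.215, and 0.00889 with the replicate number as a block, and the difference was 0.59 with the row names realigned and 0.05 with the names as deposited. By camera the interferon-stimulated, monocyte, NF-kB and complement lists lay higher with AsnRS, and the cholesterol synthesis and cell cycle lists lay lower. Each of these calls was lost with an estimated correlation (adjusted p = 0.701) and by fry's directional test without the block (0.185 to 0.761), while fry with the block called the monocyte list (0.0184).

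In the interferon-stimulated list 31 of 39 genes lay above the controls, with a mean of 0.114 and an adjusted p of 2.37e-05 (adjusted p = 0.701 with an estimated correlation). The differences were 0.58 ± 0.14 for IFI6, 0.54 ± 0.08 for MX1, 0.47 ± 0.12 for IFIT3 and 0.41 ± 0.11 for IFIT1. Adjusted over the list alone, IFI6, MX1, IFIT3 and IFI27 passed, 4 of 39. The T and NK cell list had a mean of 0.051 and an adjusted p of 0.0829. The monocyte list had a mean of 0.130 over 13 genes and an adjusted p of 0.000144 (adjusted p = 0.701 with an estimated correlation), with differences of 0.32 ± 0.13 for CCR2, the receptor for CCL2, 0.28 ± 0.08 for the endotoxin co-receptor CD14 and 0.26 ± 0.12 for THBD. Its calls with AsnRS and with IL-8 rest on the same control arrays. Between AsnRS and IL-8 its mean difference was 0.033 (camera adjusted p = 0.864). The NF-kB and inflammatory list had a mean of 0.102 over 27 genes and an adjusted p of 0.00477 (adjusted p = 0.701 with an estimated correlation). In it CXCL8 lay beside PTX3 at 0.39 ± 0.13 and TNFAIP2 at -0.37 ± 0.08. The complement and Fc receptor list had a mean of 0.063 over 19 genes and an adjusted p of 0.0226 (adjusted p = 0.701 with an estimated correlation), with CR1 at 0.31 ± 0.07. Without control replicate 2 the mean was 0.066 for the interferon-stimulated list and 0.029 for the complement list, which was at 0.096 without control replicate 1.

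All 16 genes of the cholesterol synthesis and uptake list lay below the controls with AsnRS, by a mean of -0.075, with an adjusted p of 0.00236 (adjusted p = 0.701 with an estimated correlation). DHCR7 differed by -0.23 ± 0.10 and SQLE by -0.15 ± 0.07. The cell cycle list had a mean of -0.072 and an adjusted p of 0.00477 (adjusted p = 0.701 with an estimated correlation), and CENPF, a kinetochore protein, differed by -0.21 ± 0.08. In all, 6 of 33 lists passed between AsnRS and control. Without AsnRS replicate 2, and without control replicate 1, 2 lists passed, interferon-stimulated and monocyte. The complement list was also lost without control replicate 2 or AsnRS replicate 1, at means of 0.029 and 0.063. With no filter on low genes its mean was 0.044 and it was not called (adjusted p = 0.208). With the 60th percentile filter the NF-kB and cell cycle lists were not called, at means of 0.035 and -0.036 (adjusted p = 0.561 and 0.233). The cell cycle mean was -0.032 and -0.112 without control replicates 1 and 2, and -0.110 and -0.034 without AsnRS replicates 1 and 2. The cholesterol mean was -0.041 without AsnRS replicate 2.

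**Figure D2:**
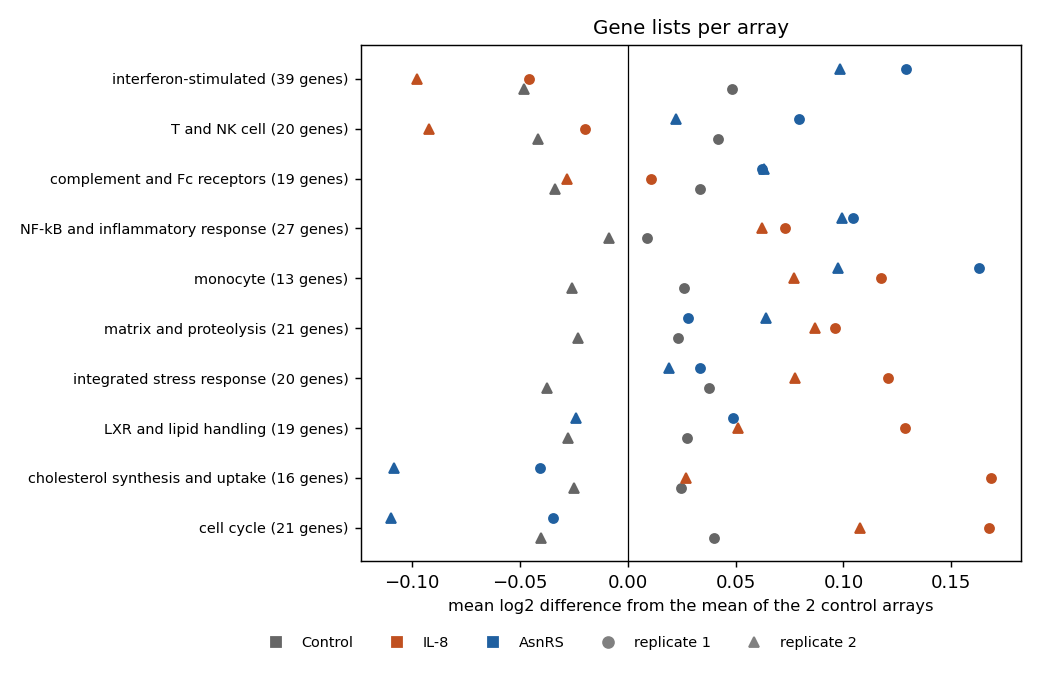
Mean log2 difference of each gene list from the mean of the 2 control arrays (horizontal axis), for the 10 lists that passed in at least 1 comparison (rows). Colours are the groups, circles are replicate 1 and triangles are replicate 2. For interferon-stimulated genes the AsnRS arrays lie at 0.129 and 0.0983 and the IL-8 arrays at -0.046 and -0.0977, and for cell cycle genes the IL-8 arrays lie at 0.167 and 0.108.

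No gene passed over all genes by limma between AsnRS and control. An unadjusted p under 0.05 was seen for 337 genes, where evenly spread p-values would give 589. That figure is not the chance count of this fit, in any of the comparisons. A number effect common to the groups cancels in the differences but widens the spread, so p-values run large. The median SE was 0.084, and 0.071 with the block. With the replicate number as a block 1 gene passed, CXCL8, and 711 had an unadjusted p under 0.05. Besides CXCL8, IFI6 and MX1, the largest differences among genes whose groups did not overlap were 0.76 ± 0.30 for RBM48, 0.61 ± 0.18 for the eosinophil chemokine CCL24 and 0.53 ± 0.09 for CLEC5A. On the lower side they were -0.88 ± 0.31 for CTSZ, -0.83 ± 0.24 for PPP3R1, -0.64 ± 0.33 for APP, -0.50 ± 0.14 for HIRA, -0.45 ± 0.19 for SMG1P5 and -0.43 ± 0.18 for ATF6B.

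The IL-8 receptors themselves differed little. For CXCR1 the difference from control was -0.12 with AsnRS (95% interval -0.43 to 0.18) and 0.03 with IL-8 (-0.28 to 0.34). For CXCR2 it was 0.09 with AsnRS (-0.16 to 0.34) and 0.00 with IL-8 (-0.25 to 0.25). NARS1, the human cytosolic counterpart of the nematode enzyme, had a difference of 0.00 with AsnRS (-0.18 to 0.18) and -0.07 with IL-8 (-0.25 to 0.11). Except for NARS1 with IL-8, the direction of these values depended on which array was left out. The 17 cytosolic aminoacyl-tRNA synthetase genes had a median of 0.020 with AsnRS and -0.033 with IL-8, with adjusted p of 0.826 and 0.830.

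The dendritic cell maturation list did not pass by camera with either stimulus. The median over 28 genes was -0.033 with AsnRS (adjusted p = 0.285) and -0.050 with IL-8 (adjusted p = 0.470). Single members did pass with IL-8 when adjusted over the list alone. They were the adhesion molecule ICAM1, at 0.37 ± 0.07, and, with the replicate number as a block, also PDCD1LG2 at -0.27 ± 0.07 and IL7R at -0.26 ± 0.07. By fry's test of change in either direction the list had an adjusted p of 0.166 with IL-8, and of 0.0191 with the block. The 14 MHC class II genes had medians of 0.030 and 0.006, and the 22 genes of cytokines and receptors that direct T cell responses had medians of 0.004 and -0.039, with adjusted p from 0.285 to 0.942 over these lists. With IL-8 the means of the last 2 lists, -0.013 and 0.006, had the opposite sign of their medians. With the block and adjusted over the list alone, IL10, IL6 and TNFSF10 of the T cell response list passed with AsnRS, at 0.34 ± 0.07, 0.26 ± 0.07 and 0.48 ± 0.08. These members of both lists are named after their values were seen.

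The effects of AsnRS and IL-8 on the 11785 genes had a Pearson correlation of 0.415 across genes, which are not independent replicates. Both effects use the same control arrays, and unchanged groups simulated against shared controls gave 0.5. The covariance was 0.00462, against 0.00297 in a simulation with the spread within replicate numbers and 0.00532 in one with the spread between all arrays. Each group holds both replicate numbers, so a number effect common to the groups cancels in these differences, while the spread between all arrays includes it. What the excess of 0.00165 over the spread within numbers reflects was not tested. Without control replicate 1 the correlation was 0.666, where unchanged groups simulated with 1 shared control array gave 0.669. At an unadjusted p under 0.05, 48 genes were higher with both stimuli and 45 lower with both, where independent lists would share 6.2 and 5.3. Unchanged groups simulated against shared controls, with lists of the same sizes, shared 62.1 and 50.4 on average over 100 simulations, with ranges of 48 to 80 and 37 to 62. In fits with the replicate number as a block, of the data and of simulations alike, 134 genes were higher and 104 lower with both, against 102 to 144 and 105 to 148. Neither overlap exceeded the simulated range in either fit, and with the block the lower overlap lay below it. The simulated groups held no effects, yet their lists were cut to the observed sizes, so this does not exclude a shared response. The AsnRS effect in replicate 1 and the IL-8 effect in replicate 2, which share no array, had a correlation of 0.057, and the reverse pairing gave -0.015.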

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

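All tests of explanations below were chosen after the result was seen. A row outside the comparisons stood out. It is named as a probe set of DENND4B and is one of the rows left out because names and values appeared out of step. Between AsnRS and IL-8 it differed by 1.43 on the log2 scale, with an adjusted p of 0.0346 among the 303 such rows above the level filter. The row deposited under the name of another probe set of CXCL8, also among those left out, was flat. Its difference was 0.0534 between AsnRS and control and -0.03 between AsnRS and IL-8.

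As deposited, CXCL8 thus has one row that differs between the stimuli and another that does not, and displaced row names are a candidate explanation. Over the 6 arrays, the CXCL8 row used here had a correlation of -0.124 with the flat row. With the row named DENND4B it was 0.945. Over the displaced probe sets, the value 1 row further on had a correlation of 0.3328 with the other probe sets of the named gene, against 0.0386 in place, and CXCL8 read that way holds the row with the difference of 1.43. A general maturation of the cells, as bacterial products in a recombinant protein could start, is argued against by the maturation list, whose median was -0.033 with an SD of 0.10 among members where CXCL8 differed by 0.91. Bacterial products that act short of such a maturation cannot be told apart from a response to AsnRS itself, since no control protein was run. With AsnRS the NF-kB and inflammatory list lay above the controls by a mean of 0.102 (camera adjusted p = 0.00477, and 0.701 with an estimated correlation). CXCL8 is itself a member, so the list partly restates the result. With the 60th percentile filter, which removes CXCL8, the mean was 0.035 (adjusted p = 0.561). Of its 27 members 17 lay above 0 and 10 below. Adjusted over the list alone, 2 members passed, CXCL8 and TNFAIP2, which was lower at -0.37. With the replicate block 9 passed, these 2, IL6, ICAM1 and PTX3 among them. With IL-8 the NF-kB and inflammatory list also lay above the same controls, by a mean of 0.068 (camera adjusted p = 0.0377, and 0.815 with an estimated correlation). Between AsnRS and IL-8 its mean difference was 0.034 (camera adjusted p = 0.786). The interferon-stimulated list lay above the controls by 0.114 with AsnRS.

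Interferon-stimulated genes lay higher with AsnRS than with IL-8 at camera's preset correlation, but not past the threshold with an estimated correlation (adjusted p = 0.637) or by fry's directional test (0.447). A single deviating array is argued against: without each of the 6 arrays the highest adjusted p of the list at the preset correlation was 7.25e-07, and the mean difference was 0.175 in replicate 1 and 0.196 in replicate 2. More T and NK cells in the AsnRS wells cannot be told apart from a change in the dendritic cells. The cultures began from CD14-positive cells, a selection that would lower the share of T and NK cells, but how many stayed is not known here. The T and NK cell list differed by a mean of 0.107, led by GZMA, CD2 and NKG7 at levels of 6.92, 7.13 and 6.67 with AsnRS. GNLY and KLRD1 each differed by 0.27, and 7 of the 20 members lay below 0. With the replicate number as a block and adjusted over the list alone, CD2, GNLY, GZMA, NKG7 and KLRD1 passed. Of the T cell genes, CD3D differed by 0.19 ± 0.07, LCK by -0.08 ± 0.07 and CD3E by -0.07 ± 0.08. Values of T cell genes do not decide whether there were more NK cells. A response of the cells to AsnRS stays open, as untested.

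Cell cycle genes lay higher with IL-8 than with AsnRS at camera's preset correlation, but not past the threshold with an estimated correlation (adjusted p = 0.637), by fry's directional test (0.447) or with the 60th percentile filter (0.242). A single deviating array is argued against here too, with a highest adjusted p of 2.82e-06 over the 6 fits without 1 array at camera's preset correlation. More dividing T and NK cells in the IL-8 wells, whose share after the CD14 selection is not known here, cannot be told apart from other sources. The T and NK cell list lay on the AsnRS side by 0.099 in replicate 1 and 0.114 in replicate 2, and CD3D by 0.19 ± 0.07. But LCK and CD3E lay on the IL-8 side, at low levels, and 7 of the list's 20 members lay below 0. Other dividing cells that the lists do not hold, and division of the dendritic cells or their precursors, stay open. This may be a response to IL-8, a hypothesis found and tested on the same 6 arrays.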

How the results depend on the processing

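The row names as deposited and realigned, the arrays of each replicate number alone, and the replicate block joined with another change were chosen after seeing the data. All differences are limma log2 values, and the cause of a change was not tested unless the setting itself shows it. Of 2692 values of named genes, 2491 kept their direction and side of the threshold, 165 newly passed, 11 no longer passed and 25 reversed. Of 519 values of called lists 390 kept the call, 129 lost it and 0 reversed.

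With no filter on low genes, the 60th percentile filter, every probe set tested on its own, only the compared groups in the fit, or the row names deposited or realigned, 0 genes were called between AsnRS and IL-8. The 60th percentile filter removes CXCL8, so it has no value there. With quantile normalization again or median centring 2 were called, CXCL8 and PCLAF. Lists called between IL-8 and control numbered 4 with no filter, with or without the replicate block, 4 with the 60th percentile filter and 5 with the mean of all probe sets. With an estimated correlation, or by fry's directional test without the block, 0 lists were called in each comparison. With the block, fry called 1 list for AsnRS (monocyte, adjusted p = 0.0184), 3 for IL-8 (lipid handling 0.0422, cell cycle and monocyte 0.0227) and 0 between them. Fry's test of change in either direction, without the block, called 2, 12 and 15. The block changed these calls. For AsnRS against control it added lists, alternative activation (adjusted p = 0.00345) and interferon-stimulated (0.0296) among them. For IL-8 against control the stress response list was no longer called (0.0725).

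With the replicate block, 1 gene was called for AsnRS against control, 6 for IL-8 against control and 6 for AsnRS against IL-8. The block ended the call of the NF-kB list for IL-8 and of the T and NK cell list between the stimuli, and it changed no other list call. Without each array in turn and no block, calls were 0 to 0 in all 3 comparisons, and a lone array of a group was assumed to vary like the others. Lists called were 2 to 6 for AsnRS, 3 to 8 for IL-8 and 4 to 6 between them, and the correlation of effects was 0.285 to 0.666 (unchanged groups with 1 shared control array gave 0.669), and 0.495 in the arrays of replicate 2 alone.

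With the block and 1 array left out, fits have 1 residual degree of freedom. Calls ran from 0 to 48 for AsnRS against control, with 18 without control replicate 1, 3 without control replicate 2 and 48 without either IL-8 array. For IL-8 against control they ran from 0 to 118, with 40 and 8 without control replicates 1 and 2, and 118 and 98 without IL-8 replicates 1 and 2. For AsnRS against IL-8 they were 73 without either control, 37 and 44 without IL-8 replicates 1 and 2 and 0 without either AsnRS array. Lists called were 4 to 5, 3 to 7 and 3 to 5, with 3 and 5 for IL-8 against control without control replicate 1 and IL-8 replicate 1, and 3 between the stimuli without IL-8 replicate 2.

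Some values reversed. With the names as deposited CXCL8 was 0.09 for IL-8 against control and -0.03 for AsnRS against IL-8, and SERPINA1 was 0 for IL-8, since another row then bears the name. HMGCS1 for IL-8 was -0.07 with the mean of all probe sets, and CXCR2 for IL-8 -0.01 with median centring. Without 1 array in turn, AsnRS against control ran from -0.28 to 0.04 for CXCR1 and from -0.01 to 0.19 for CXCR2. NARS1 ran from -0.04 to 0.04, with 0.02 without control replicate 1. CCNA2 ran from -0.39 to 0.07. IL-8 against control ran from -0.13 to 0.19 for CXCR1, with -0.07 without IL-8 replicate 1, and from -0.1 to 0.1 for CXCR2. AsnRS against IL-8 ran from -0.01 to 0.19 for CXCR2 and from -0.04 to 0.58 for PSPH.

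With the block as well, CXCR2 without control replicate 1 was -0.1 for AsnRS and -0.19 for IL-8. Without control replicate 2, NARS1 was 0.02 and CCNA2 0.01 for AsnRS, and CXCR1 -0.03 for IL-8. CXCR2 for IL-8 was -0.11 without IL-8 replicate 1. Without IL-8 replicate 2, CXCR1 for IL-8 was 0 and CXCR2 between the stimuli -0.03. CCNA2 for AsnRS was 0.09 without AsnRS replicate 2.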

Other observations

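The replicate number went with larger differences than either stimulus. With the groups as a term, 281 of 11785 genes differed between numbers 1 and 2, 214 higher and 67 lower in number 2, and 22 by at least 1 on the log2 scale. Between the stimuli and control, 0 genes with AsnRS and 2 with IL-8 reached a difference of 1, CLEC5A and ERGIC1. ERGIC1, named here after its values were seen, differed by -1.01 ± 0.57 (SE).

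Some genes had differences of the same sign with both stimuli relative to control. CTSZ, a lysosomal cathepsin, differed by -0.88 with AsnRS and -0.76 with IL-8, APP by -0.64 and -0.82, and RBM48 by 0.76 and 0.62. None of these 3 passed the threshold in either comparison, with or without the replicate number as a block, and both differences rest on the same control arrays. CLEC5A was 0.53 above control with AsnRS and 1.07 with IL-8, and the difference between the stimuli was -0.54 ± 0.09 (SE), with an adjusted p of 0.406. The alternative activation list, which holds IL-4 targets, had medians of 0.017 and 0.030 with camera adjusted p of 0.205 and 0.382. By fry's test of change in either direction its adjusted p was 0.468 and 0.0168, and 0.00345 and 0.0191 with the block. With the block and adjusted over the list alone, 3 members passed with each stimulus.

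Markers of other blood cells outside the T and NK and monocyte lists did not pass by camera in any comparison. By fry's test of change in either direction the macrophage list passed for IL-8 against control (adjusted p = 0.0168) and for AsnRS against IL-8 (0.00855). With the replicate number as a block and adjusted over the list alone, APOC1, SLC40A1 and TUBB1 passed as single members, named here after their values were seen. With AsnRS and IL-8 against control, the macrophage list had means of 0.052 and 0.048 (adjusted p = 0.0874 and 0.129), the neutrophil list 0.021 and 0.014 (0.934 and 0.886) and the platelet list -0.016 and 0.052 (0.759 and 0.462). The plasmacytoid dendritic cell list had means of -0.041 and -0.035 (0.354 and 0.807), and the B cell and plasma cell list, with 5 genes, 0.009 and 0.031 (0.934 and 0.611).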
